A study of Mus musculus with 2 samples.

How the data were processed

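DNase-seq of cerebellum tissue from female B6CASTF1/J mice was given for 2 libraries of 1 group, with the replicate numbers in the labels. Per the labels, the genome build was mm10; the aligner, the caller of regions, the footprint tool and their versions were not given in the sources used here. For each library the authors deposited 2 lists of accessible regions, called per library without pooling, a list of footprints and a list of bases with a false discovery rate. In the deposited region lists each region carries a signal value, called strength here, which the authors computed; all values were whole multiples of 1 step per library within a tolerance of 0.05 of a step, and the scale was not given in the sources used here. The deposited footprint lists carry a score that is 0.01 in every line and was not used as a measurement. The authors' lists of bases give an FDR, a p-value corrected for multiple testing, and hold values below 0.05. The values show how the lists relate: every region of the shorter list held a base with an FDR of 0.001 or less, and every region of the longer list a base below 0.05. Read depth was not given in the sources used here, so precision is given as the spread between libraries and as intervals for counting error. Each library was measured separately.

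The shorter list was the main one. Regions on the mitochondrial genome and on unplaced sequences were left out. Coordinates are 1-based on mm10. The reference was the GRCm38 sequence with its GENCODE annotation of 55413 genes, of which 21938 are protein-coding. Regions of the libraries were compared at an overlap of at least 1 bp in both directions. The comparison was set against 20 shuffles of 1 list within each chromosome, made with bedtools 2.31.1. Shared sites were stretches of the merged lists that held a region of both libraries, with the strongest region of each library as the strength. Regions were placed by their midpoint at promoters (within 1000 bp of an annotated transcription start), other exons, introns or intergenic sequence, and shares were set beside those of the genome. A share in 1 library has a Wilson interval.

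Except where a later choice is stated, the main choices, the tests, the gene lists and the sequences were set before the data were examined. The 23 lists were granule neuron, Purkinje neuron, cerebellar interneuron, unipolar brush and deep nuclear neuron, Bergmann glia and astrocyte, oligodendrocyte lineage, microglia, endothelial and mural, choroid plexus and ependyma, forebrain neuron, liver, striated muscle, blood, housekeeping, neuronal synapse, immediate early, circadian clock, imprinted, glial reactivity and lysosome, X-linked, Y-linked, olfactory receptor and Hox genes. For promoters, the share of a list with a region was set against 10000 random lists of the same size, drawn from protein-coding genes in 10 bins of promoter CpG observed over expected (500 bp either side of the start). For distal regions, the median number outside promoters in the gene body and 10 kb either side was set against random lists in 10 bins of locus length. P-values are two-sided, the smallest possible is 2e-04, and they were adjusted by Benjamini-Hochberg over the 23 lists within a library. A list was called where adjusted p was below 0.05 on the same side in both libraries. These p-values describe the lists within these libraries. On simulated lists of 18 genes, 3.50% of 200 lists without an effect and 76.0% of 200 raised lists had p below 0.05. In raised lists the odds of a promoter region were raised for every member. These simulated p-values were not adjusted over lists and did not have to pass in both libraries. The 76.0% is therefore not the power of a call. The median of distal regions was not simulated.

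Footprints were counted inside regions by their midpoint. Exact matches of 24 fixed consensus sequences on both strands were counted per Mb. They were counted in all footprints, inside or outside regions, and in the regions with footprints removed. The ratio of these densities has a 95% interval from the counts. Regions per Mb on chromosomes X and Y were set against autosomes. Exact copies of stretches of 32 bp were looked up on the reference chromosomes and the mitochondrial genome, a search added after the strongest sites had been seen. Inexact copies and unplaced sequences were not searched. Genes and sites were named by a fixed rule: the 3 members of each list with the strongest promoter region by mean rank and up to 2 without one in either library, the 10 strongest shared sites outside and at promoters, the 20 loci with the most shared distal sites and the 20 with the most per kb among those with at least 5, the 5 most and 5 least enriched sequences, and Xist, Kdm5d, Uty, Ddx3y and Eif2s3y. The text gives a selection of these, and some named items are not reported here; genes that share a promoter region with a named gene, Gabra6 and the genes that only the closing section names were chosen after their values were seen. Region strength was compared between libraries by rank and by correlation.

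Alternatives tried were the longer region list, regions at or above the median strength, reciprocal overlap of 50%, equal numbers of regions per library, promoters of 500 and 2500 bp, protein-coding transcripts alone, the 5′ end of the gene alone, random lists not matched, random lists without olfactory receptors, flanks of 50 kb and none, matching also on regions within 1 Mb, footprints found in both libraries or outside promoters, flanks of 50 bp and shuffled sequence (dinucleotides kept) as background, regions per gene, and each library alone. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with a fixed random seed of 20. Steps that compute p-values or shuffled sequence were tested on simulated data first.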

Results

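DNase-seq marks DNA that the enzyme DNase I can cut in nuclei, and so maps accessible promoters, enhancers and insulators. It was applied to the cerebellum of female F1 hybrid mice of the strain B6CASTF1/J, aged 18 to 20 months. There was 1 group of 2 libraries, named replicate 1 and replicate 2, and no second tissue, age or treatment, so each measure was set against the rest of the genome or against other genes of the same libraries. The libraries had separate biosample records and shared 1 donor record, and nothing in the labels said that they came from separate animals, so the spread between them may be technical. Values with ± are the mean and SD of the 2 libraries (n = 2). The strength of a region is the authors' own signal value, whose scale was not given in the sources used here. Every strength was a whole multiple of a step of 0.00570 in replicate 1 and of 0.00389 in replicate 2. Read depth was not given in the sources used here. Were strength scaled to library depth, the ratio of the steps, 1.47, would be the depth of replicate 2 relative to replicate 1.

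Replicate 1 had 65238 accessible regions and replicate 2 had 103596 (84417 ± 27123, median width 200 bp in both). Their widths summed to 15.8 Mb and 23.9 Mb. Regions of 1 library overlap each other in places, so the sums count some bases more than once. Counts of regions take each listed region separately. Outside promoters, an exon of Cers5, a ceramide synthase gene, held the strongest site without an exact 32 bp copy elsewhere on the reference chromosomes. It lay on mm10 chromosome 15, 99735641 to 99735920, with a strength of 32.2 ± 4.25. An intron of Vps37c, which encodes a subunit of the endosomal sorting machinery, held another (chromosome 19, 10709481 to 10709660, 21.8 ± 5.85). One more lay 4945 bp from Txn2, the gene of mitochondrial thioredoxin (20.6 ± 3.45), and a site near Ptma, 39115 bp away, reached 17.4 ± 4.61. A site in an annotated exon, where the genes C87436 and A430078I02Rik overlap, carried 2 copies of TGACGTCA, the site of CREB-type factors. Both copies lay inside footprints of both libraries (chromosome 6, 86472201 to 86472480, 17.4 ± 5.86). The site 34056 bp from Foxk1 carried GCGCATGCGC, the NRF1 sequence, in a footprint of both (chromosome 5, 142367398 to 142367407; region strength 17.3 ± 2.03). Among the 10 strongest promoter sites, those of the centromere factor gene Hjurp (26.3 ± 8.08) and the nuclear pore gene Nup107 (23.8 ± 7.81) had no exact copy either. The Nup107 site also had an NRF1 sequence in footprints of both libraries.

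Of these 20 sites, the 10 strongest outside promoters and the 10 strongest at promoters, 12 had an exact copy elsewhere for at least 50% of their stretches of 32 bp, against 1.61% of such stretches in 500 random shared sites. They included the sites in Lars2 (36.3 ± 6.58, 61.5% copied), in Il31ra (23.8 ± 1.22, 75.2%), 458 bp from Gm21887 on chromosome X (43.0 ± 8.19, 100%) and at Dynlt1b (28.0 ± 12.3, 51.0%). The highest strength of all, 56.3 ± 8.55, was on chromosome 17 from 39846781 to 39846900, 117 bp from the start of Gm42418, and 100% of it was copied.

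How far the libraries found the same chromatin was the one comparison between samples. Of the regions of replicate 1, 87.7% overlapped a region of replicate 2 by at least 1 bp, and 55.1% of those of replicate 2 overlapped one of replicate 1. With positions shuffled within chromosomes, the overlaps averaged 1.82% and 1.15%. Merging both lists gave 106922 sites, of which 54009 were accessible in both libraries, 7703 in replicate 1 alone and 45210 in replicate 2 alone. Among the 10000 strongest regions, 99.8% and 99.6% were found in the other library. Regions found in 1 library alone were weak, with a median strength of 0.405 against 1.44 for shared regions in replicate 1 and 0.478 against 2.03 in replicate 2. Promoter, intergenic and intronic regions were shared in 90.7%, 89.7% and 83.2% of cases in replicate 1, and in 70.8%, 53.2% and 43.9% in replicate 2. Across the 54009 shared sites, strength correlated with a Spearman's rho of 0.971 and a Pearson's r of log2 strength of 0.970; these are correlations across sites, which are not independent replicates. Strength was higher in replicate 2 by a median of 0.48 on the log2 scale.

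**Figure D1:**
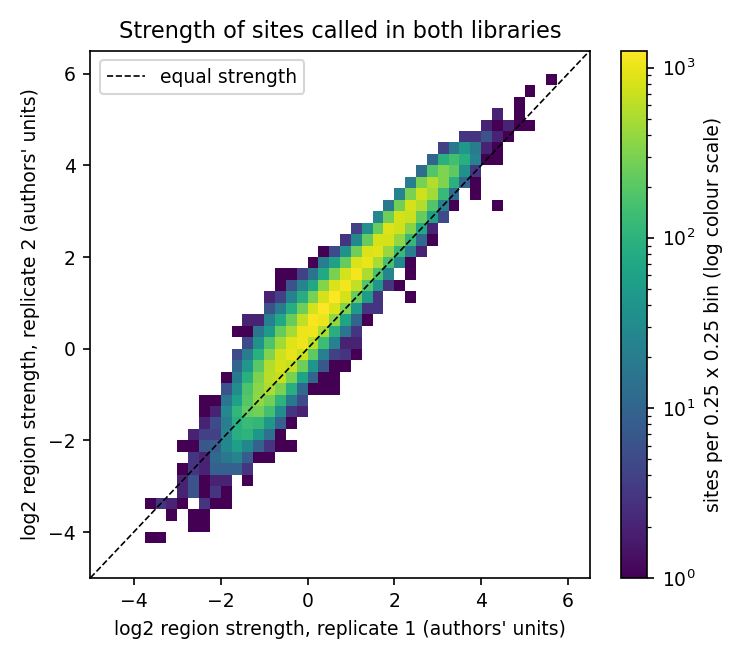
Each cell counts sites accessible in both libraries by their log2 strength in replicate 1 (horizontal axis) and replicate 2 (vertical axis), both in the authors' units, with a log colour scale. The 54009 sites lie along a band 0.48 above the dashed line of equal strength at the median. The band lies closer to that line among weak sites than among strong ones.

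Promoters, taken as 1 kb either side of an annotated transcription start, held 36.9 ± 5.60% of accessible regions and 6.05% of the genome, a 6.09 ± 0.925-fold excess. The excess was 8.77-fold with promoters of 500 bp either side, 3.56-fold with 2500 bp and 8.93-fold with protein-coding transcripts alone. With equal numbers of regions per library it was 6.57 ± 0.244-fold, a smaller spread between libraries. Exons away from promoters held 6.01 ± 0.353% of regions and 3.18% of the genome. Introns held 34.3 ± 4.30% of regions against 38.3% of the genome, and intergenic sequence 22.9 ± 0.944% against 52.4%. The share at promoters was 40.8% in replicate 1 (Wilson 95% interval 40.4 to 41.2%, counting error only) and 32.9% in replicate 2 (32.6 to 33.2%), so the libraries differed by more than counting error. Promoter regions were stronger than intronic ones in both libraries, with medians of 1.88 and 0.992 in replicate 1 and 1.65 and 0.781 in replicate 2. Of 21938 protein-coding genes, 13120 had an accessible promoter in replicate 1 and 14049 in replicate 2 (61.9 ± 2.99%), and 13088 had one in both.

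Promoters of cell types and gene groups were examined with 23 gene lists, each set against 10000 random lists of protein-coding genes matched on promoter CpG content. Promoters of granule neuron genes, the most numerous neurons of the cerebellum, were accessible in 97.7 ± 3.21% of 22 genes against 73.8% in random lists. The strongest were at Cbln3, a granule cell cerebellin (10.0 ± 3.32), Nfia, a transcription factor of the NFI family (9.28 ± 2.73), and Neurod1, a neuronal differentiation factor (8.21 ± 2.80). The Cbln3 region also lay within 1 kb of the start of Khnyn and the Neurod1 region within 1 kb of that of Cerkl, while the Nfia region was at an internal start 138157 bp from the 5′ end of the gene. The member without an accessible promoter in replicate 1 was Gabra6, a GABA receptor subunit gene named after its values were seen. Neuronal synapse genes were accessible at 97.9 ± 2.95% of 24 promoters against 75.1%. They were led by the calcium channel gene Cacna1a (11.0 ± 4.09), with the synaptic vesicle gene Vamp2 at 10.1 ± 3.57. The Cacna1a region was at an internal start 251091 bp from the 5′ end, close to the 3′ end of the gene. Both lists lay above the random lists in both libraries (adjusted p 0.00288 and 0.00115 for granule neurons, 0.00288 and 0.00184 for synapse genes, Benjamini-Hochberg over the 23 lists, two-sided). The synapse call was lost when only the 5′ end of each gene was counted as its promoter.

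Below the random lists were 4 groups. Hox genes, which pattern the body axis, had an accessible promoter in 6.41 ± 1.81% of 39 genes against 82.9%; Hoxa7 (3.81 ± 0.0969) and Hoxc5 (1.09 ± 0.272, at an internal start 46268 bp from the 5′ end) had one in both libraries, and Hoxa10 in neither. With the 5′ end of each gene alone, the Hox share was 3.85%. Olfactory receptor genes had one in 0.794 ± 0.499% of 1134 genes against 12.5%. None of the 8 Y-linked genes, Ddx3y, Eif2s3y, Kdm5d and Uty among them, had one, against 73.8%. For these 3 lists p was 2e-04 in both libraries, the smallest that the random lists can give, and adjusted p was 0.00153 and 0.00115. Random lists draw genes from the whole genome, whereas many Hox and olfactory receptor genes lie side by side. The p-values treat such neighbours as independent and so overstate the evidence. Cerebellar interneuron genes were accessible at 52.9 ± 8.32% of 17 promoters against 83.2% (adjusted p 0.00288 and 0.0115). Cdh22, a cadherin gene (3.36 ± 0.825), Pvalb, the parvalbumin gene (1.61 ± 0.597), and Nxph1, a neurexin ligand gene (1.60 ± 0.550), the latter 2 at internal starts, had the strongest of these, and Grm2 and Pax2 had none. The interneuron call was lost with promoters of 2500 bp either side, with equal numbers of regions per library and with random lists not matched on CpG.

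The other 17 lists were not called in both libraries, although some were under other settings. With promoters of 500 bp either side, microglia (11.1%), endothelial and mural (20.6%) and striated muscle genes (11.1%) were called below random lists. Random lists not matched on CpG placed microglia, liver, striated muscle and blood genes below and housekeeping, immediate early and circadian clock genes above. Purkinje neuron genes had an accessible promoter in 81.8 ± 6.43% of 22 genes against 67.1% (adjusted p 0.222 and 0.114). Itpr1, the inositol trisphosphate receptor gene (8.28 ± 2.42), and Plcb4, a phospholipase gene (5.72 ± 1.36), led them, whereas Pcp2 and Ppp1r17 had no accessible promoter and no distal region in either library. Unipolar brush and deep nuclear neuron genes stood at 63.6 ± 12.9% against 71.6%, with Eomes at 2.01 ± 0.303. Glial lists stood at 58.3 ± 19.6% against 63.2% for Bergmann glia and astrocytes (Gfap 3.80 ± 0.717, Slc1a2 3.15 ± 0.689) and 47.2 ± 11.8% against 59.2% for the oligodendrocyte lineage (Fa2h 3.92 ± 1.37, Mbp 3.15 ± 1.30). Microglia stood at 16.7% in both libraries against 37.0% (Aif1 and C1qa none), glial reactivity and lysosome genes at 34.4 ± 13.3% against 42.0% (Ctsd 9.70 ± 3.52; C4b and Cd68 none), endothelial and mural genes at 26.5 ± 12.5% against 54.3% (Egfl7 2.06 ± 0.282, at an internal start within 1 kb of a start of Gm20532; Cdh5 none) and choroid plexus and ependyma genes at 29.2 ± 17.7% against 41.0% (Foxj1 3.74 ± 0.566). Replicate 1 alone placed endothelial and mural genes (17.6%, adjusted p 0.00276) and forebrain neuron genes (40%, adjusted p 0.00230) below random lists; in replicate 2 the shares were 35.3% (adjusted p 0.117) and 75% (adjusted p 0.717). With equal numbers of regions per library both lists were called below random lists, at 11.8% and 35%.

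Of the remaining lists, liver genes stood at 10.5% in both libraries against 28.2%, blood genes at 22.2% in both against 28.6%, striated muscle genes at 27.8 ± 7.86% against 42.6% and forebrain neuron genes at 57.5 ± 24.8% against 79.8%. Alb and Ahsg in the liver list had no accessible promoter in either library. The strong region at the liver gene Apoh (11.2 ± 4.64) also lay within 1 kb of a start of Prkca, and that at the muscle gene Mylpf (6.06 ± 2.24) within 1 kb of a start of Tbc1d10b. All 18 housekeeping, 19 immediate early and 17 circadian clock genes had an accessible promoter in both libraries, with random means of 88.1%, 85.4% and 89.0%. Even at 100%, p against the matched random lists was 0.235, 0.0998 and 0.295 in replicate 2. These lists therefore could not be called above random lists matched on CpG. The highest strengths were at Rplp0 (18.1 ± 4.99) and Eef2 (15.6 ± 5.40) for protein synthesis, Egr1 (14.3 ± 4.28) and Jun (12.6 ± 4.38) for the early response to stimulation, and Tef (14.4 ± 4.95), Nr1d1 (14.2 ± 4.30) and Per2 (13.3 ± 4.58) for the clock. Imprinted genes stood at 76.1 ± 3.07% against 69.1%, with Inpp5f at 7.49 ± 2.69 and Peg3, whose region also lay within 1 kb of a start of Usp29, at 6.03 ± 2.54; Cdkn1c and Dlk1 had none. The 10 X-linked genes stood at 90% in both libraries against 77.5%.

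**Figure D2:**
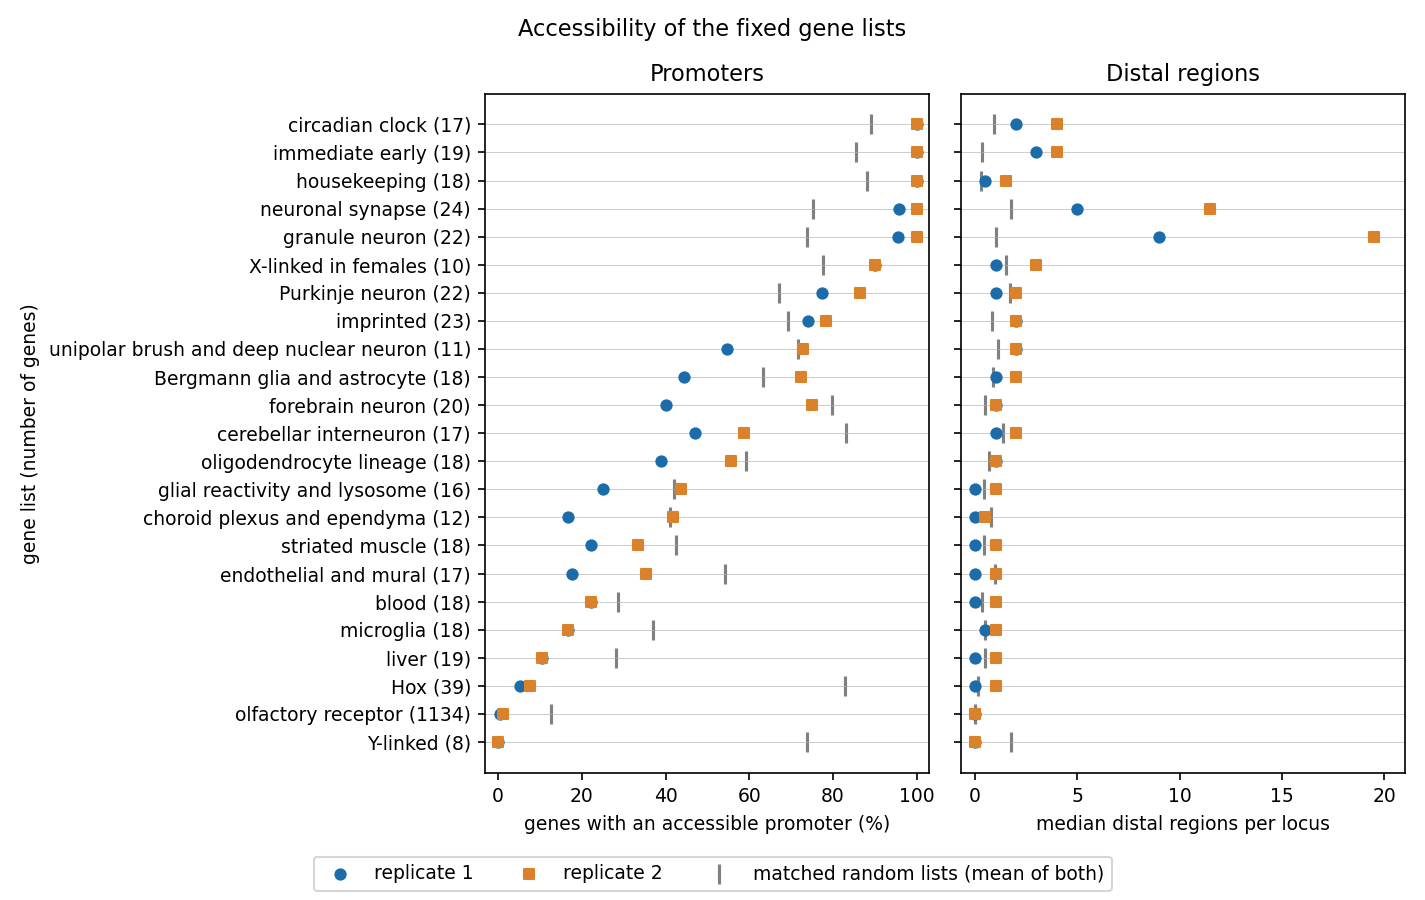
Left, the percentage of each fixed gene list with an accessible promoter; right, the median number of accessible regions outside promoters per gene locus; circles are replicate 1, squares replicate 2 (drawn over the circle where both are equal) and grey bars the mean of matched random lists. Granule neuron genes stand at 97.7% on the left and at a median of 14.3 regions on the right, against 73.8% and 1.03 in random lists.

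Accessible regions away from promoters were counted in each gene body and 10 kb either side, since such regions hold most enhancers. Granule neuron genes had a median of 14.3 ± 7.43 of them against 1.03 in random lists matched on locus length, neuronal synapse genes 8.25 ± 4.596 against 1.75, and immediate early genes 3.50 ± 0.707 against 0.352. For all 3 lists p was 2e-04 in both libraries, the smallest the random lists can give, and adjusted p was 0.00153. Nfia had 24 ± 9.90 distal regions, Cacna1a 30.0 ± 12.7 and Egr1 9 ± 2.83. None of the other 20 lists was called in both libraries; their medians ran from 0 for Y-linked and olfactory receptor genes to 3 ± 1.41 for circadian clock genes, with 1.5 ± 0.707 for Purkinje neurons. The granule neuron median was 9 in replicate 1 and 19.5 in replicate 2, and that of synapse genes 5 and 11.5. With flanks of 10 kb the random mean of olfactory receptor genes was 0 in both libraries, so a call below was not possible. With flanks of 50 kb olfactory receptor genes were also called, below random lists.

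Single loci ranked by distal sites found in both libraries were led by long genes. After Gm20388 (177 sites), annotated over 4455 kb with its flanks and overlapping Gse1, and Fgfr2 (72), annotated over 2981 kb, came the neural adhesion gene Ntm with 40 shared sites, the splicing factor gene Rbfox1 with 38, the axon growth gene Nav2 with 35, and Rbfox3, which encodes the neuronal antigen NeuN, with 31. At Ntm, 57 regions of the longer list of replicate 1 lay in 1 stretch of 41.3 kb and had no counterpart in replicate 2. Nfib, a transcription factor of the NFI family, had 24. Per kb of locus, Zic2 ranked first with 0.491 shared sites per kb, followed by Uncx (0.446), Barhl2 (0.429), Irf2bp2 (0.428) and Neurod2 (0.413), with Zic5 at 0.346 and Id2 at 0.343. Zic2, Zic5, Barhl2 and Neurod2 were members of the granule neuron list. The flanks of Zic5 and Zic2 overlap, so some regions were counted for both genes. The neighbouring Zic5 and Zic2 loci, 43.1 kb on chromosome 14 with their flanks, held 40 regions in replicate 1 and 55 in replicate 2.

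**Figure D3:**
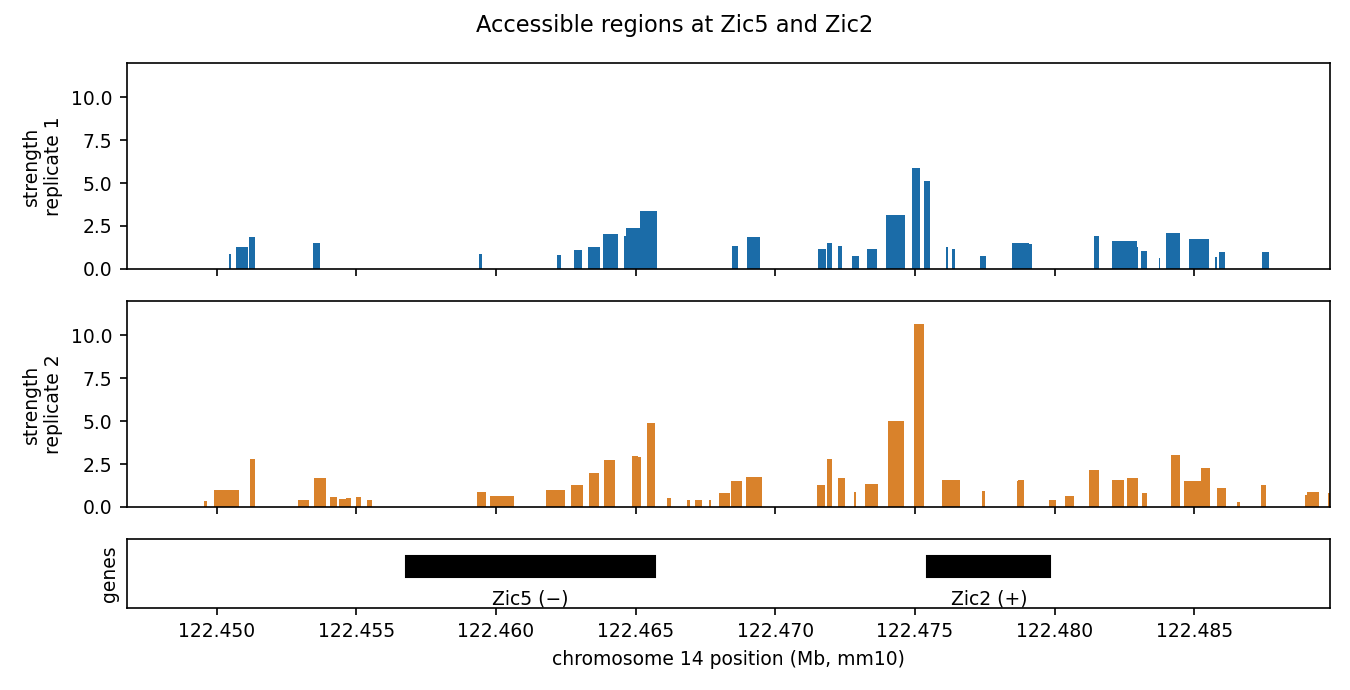
Accessible regions between 122446795 and 122489852 on chromosome 14 (mm10), with bar height giving the authors' strength in replicate 1 (top) and replicate 2 (middle) and black boxes the genes Zic5 and Zic2 with their strand. The Zic2 promoter region has a strength of 5.85 in replicate 1 and 10.7 in replicate 2.

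Footprints are short stretches protected from cutting within accessible DNA. Replicate 1 had 321764 and replicate 2 had 523180 (422472 ± 142423), with a median width of 10.0 bp in both. They lay at promoters for 44.0 ± 4.96% and inside accessible regions for 63.5 ± 2.26%, with 13.9 ± 0.114 per kb of region. At least 1 footprint was present in 86.7 ± 0.0933% of regions. Counting only footprints found in both libraries, there were 8.30 ± 2.31 per kb, and 66.3 ± 12.9% of regions had one. Regions with a footprint had a median strength of 1.47 against 0.547 without one in replicate 1, and 1.12 against 0.420 in replicate 2. Of the footprints, 63.2% in replicate 1 and 36.9% in replicate 2 overlapped one of the other library.

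Sequences bound by known factors were counted in all footprints, inside or outside accessible regions. The background was the accessible regions with footprints removed. The most enriched against the rest of the regions was that of NRF1, a regulator of nuclear genes for mitochondrial proteins, 209.8 ± 135 times as dense in footprints. That of CTCF, the insulator protein, was 79.0 ± 21.6 times as dense, NFI 37.7 ± 20.6, RFX, of ciliary genes among others, 21.02 ± 7.06, and CRE, the site of CREB, 11.3 ± 0.647. The NFI ratio rested on 11 and 10 matches in the background and was 23.1 in replicate 1 and 52.3 in replicate 2; that of RFX rested on 7 and 7 and was 16.03 and 26.01. The NRF1 ratio rested on 11 and 4 matches in the background, and was 114.1 in replicate 1 (95% interval 62.7 to 208) and 305.5 in replicate 2 (114 to 817). In footprints outside promoters CTCF had the highest ratio (93.5) and NRF1 54.0. Against shuffled footprint sequence YY1 (93.5), CTCF (56.1) and CRE (21.8) stood above NRF1 (18.4), and NFI was at 12.9. The YY1 ratio was imprecise, with 95% intervals of 28.6 to 278.7 in replicate 1 and 31.3 to 304.6 in replicate 2. RFX had no match in the shuffled sequence of replicate 1, so it had no ratio there and no call. In replicate 2 the RFX ratio was 18.5 (6.76 to 50.6). For sequences of neuronal factors, the E-box of NEUROD and ATOH factors had a ratio of 2.96 ± 0.229 and the ZIC sequence 2.00 ± 0.0892. Also enriched were SP/KLF at 8.41 ± 1.53, YY1 at 6.18 ± 1.52, ETS at 2.54 ± 0.257, CACGTG at 1.48 ± 0.109 and CAGCTG at 1.44 ± 0.0787. This made 12 enriched sequences of 24, those whose interval lay above 1 in both libraries.

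Among the sequences with a ratio, the least enriched were MEF2 at 0.384 ± 0.0342, AP-1 at 0.489 ± 0.0134, GATA at 0.497 ± 0.129, homeodomain at 0.499 ± 0.0342 and PU.1 at 0.551 ± 0.0463. With POU (0.604 ± 0.0434) and SOX (0.732 ± 0.0134) they made up the 7 depleted sequences. Against footprint sequence shuffled with its dinucleotides kept, only GATA stayed depleted, CAGCTG and SOX were not called, and the ratio of MEF2 was 5.85, that of AP-1 1.28 and that of PU.1 1.24. Neither enriched nor depleted were REST (1.27 ± 0.0734), HNF4A (1.15 ± 0.0921), SRF (0.960 ± 0.195) and ROR (0.630 ± 0.168). The ETS sequence was no longer enriched in footprints outside promoters (1.07).

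**Figure D4:**
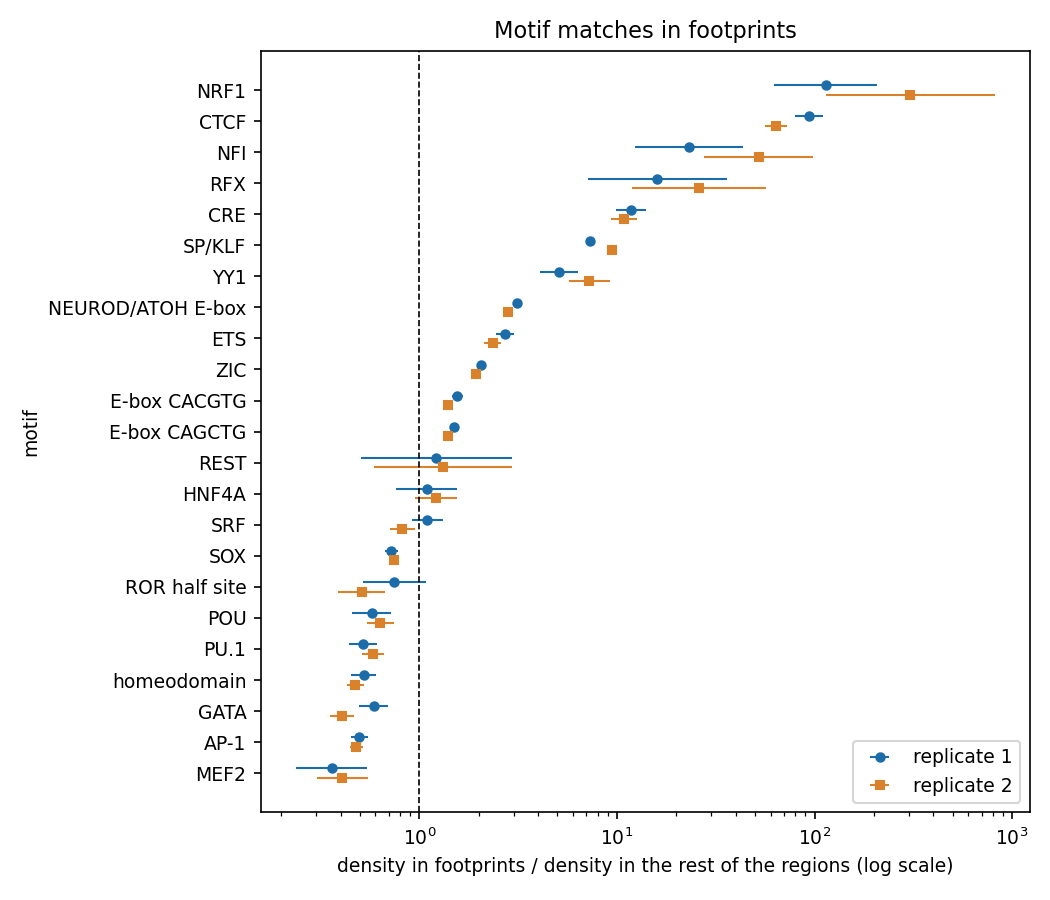
Density of each sequence with a ratio in both libraries, in all footprints divided by its density in accessible regions outside footprints, on a log axis. Circles are replicate 1 and squares replicate 2, with 95% intervals from the counts. The dashed line marks a ratio of 1. Against this background the NRF1 sequence stands highest at 114.1 and 305.5, and MEF2 lowest at 0.360 and 0.408.

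Chromosomes X and Y were examined because the labels give the animals as female. Chromosome X had 1663 regions in replicate 1 and 2482 in replicate 2, at 37.2 ± 1.67% of the autosomal density per Mb, below the least dense autosome in both libraries (10.2 against 18.2 per Mb, and 15.2 against 29.4). The promoter of Xist, the RNA that silences one X chromosome in females, was accessible with a strength of 0.980 and 1.64. The strongest promoters in the X-linked list were those of Kdm6a (16 ± 5.25), Kdm5c (9.56 ± 3.89) and Ddx3x (7.73 ± 1.91), all known to be expressed from both X chromosomes, and Dcx had none. Chromosome Y had 28 and 36 regions, 1.08 ± 0.162% of the autosomal density per Mb; per protein-coding gene Y stood at 4.53 ± 0.679% and X at 55.7 ± 2.51%. Of these, 20 and 24 lay in the last 50 kb of that chromosome with regions, between 90717610 and 90744820, with a highest strength of 19.2 and 9.44; elsewhere on chromosome Y no region was above 0.501 and 0.393. Over all chromosome Y regions, 34.0% and 29.0% of the stretches of 32 bp had a copy on another chromosome. Kdm5d, Uty, Ddx3y and Eif2s3y had neither a promoter region nor a distal one.

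Single bases at which cutting passed a false discovery rate of 0.05 covered 38.6 Mb in replicate 1 and 63.1 Mb in replicate 2. Accessible regions took in 37.9 ± 1.79% of those bases. The bases taken in equalled 96.0% and 96.6% of the summed region widths. These widths count bases of overlapping regions more than once, so the share of region bases listed was higher. The libraries shared 35.5 Mb of listed bases, 91.9% of those of replicate 1 and 56.2% of those of replicate 2 (Jaccard index 0.536).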

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

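Random lists without olfactory receptors were chosen after seeing the data; all other alternatives were set earlier. Of 344 alternative values from both libraries, 15 of those that answer a comparison stayed and 18 moved. Of the others 272 stayed, 6 lost and 14 gained a call, 12 moved and 7 changed direction. Counts of regions, footprints and calls stayed if they lay within 1.5 times the main count. Most other values without a call stayed if they lay within the SD of the libraries. Shares of overlapping regions were judged by counting error alone, and rho by resampling of sites, which are narrow limits. A count within 1.5 times can hold other members: equal numbers of regions called 7 gene lists at promoters in place of 6, of which 5 were shared. Another 168 values of 1 library alone are not counted, since with 2 libraries a value without a test lies within 1 SD of the mean by construction. The cause was not tested except where the construction of the alternative shows it.

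Regions numbered 131338 per library in the longer list and 42269 at or above the median strength, which keeps the upper part by construction. The share of replicate 1 found in replicate 2 was 72.1% with reciprocal overlap of 50%, 78.7% with equal numbers, 98.6% at or above the median strength and 83.8% in the longer list, and in the other direction 45.4%, 78.3%, 62.7% and 52.8%. Spearman's rho outside promoters was 0.950. Promoters held 28.6% of regions with a window of 500 bp and 47.5% with 2500 bp, as windows shrink or grow. Random lists not matched on CpG called 12 gene lists in place of 6. Footprints found in both libraries averaged 198242, fewer by construction. Per coding gene, X held 55.7% and Y 4.53% of the autosomal density. The longer list took in 56.8% of listed bases. Against shuffled footprint sequence the ratios of MEF2 (5.85), AP-1 (1.28), SOX (1.04), homeodomain (1.58), POU (1.81), ROR (2.91) and PU.1 (1.24) lay above 1 in place of below it, SOX without a call and ROR with none before; RFX and REST had no ratio in replicate 1, and 16 sequences were enriched and 1 depleted in place of 12 and 7.

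With each library alone, regions ranged from 65238 to 103596, the promoter share from 32.9 to 40.8%, lists called at promoters from 6 to 8 and at distal regions from 3 to 3, footprints from 321764 to 523180, enriched sequences from 12 to 12, X density from 36.0 to 38.3%, Y density from 0.968 to 1.20% and listed bases inside regions from 36.7 to 39.2%. Sharing and correlation need both libraries and have no such value. The stronger part of the footprints by score could not be taken, since the score has 1 value. No paired analysis was possible because there is 1 group. Read depth was not given, so what it limits was examined only through equal numbers of regions per library and through the blocks described below.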

Other observations

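The tests of sequencing depth, of the calling threshold, of male cells and of 1 silent X chromosome, the definition of a block and the 6 genes below were chosen after the results they bear on had been seen in part; the tests of extra DNA copies, of sequence shared with other chromosomes and of CpG content were set down before their values were seen.

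Some weak regions found in 1 library alone lay in dense blocks, of at least 10 such regions of the longer list with gaps of at most 3 kb. Replicate 1 had 160 blocks, against a highest count of 2 in 20 reshuffles of which regions were its own, and replicate 2 had 546 against 353. The blocks with the most such regions in replicate 1 were in Ntm, with 57 such regions over 41.3 kb, and Sh3gl2, with 47 over 33.6 kb, and in replicate 2 in Rims1 (55) and Maml2 (42); 79.4% and 89.6% of blocks lay in coding genes. The reshuffles did not keep region strength. In the longer list of replicate 1, regions found in it alone had a median strength of 0.3134, against 0.7465 for the whole list. Weak regions that lie close together were thus not allowed for. The 160 blocks of replicate 1, the library with the larger step of strength, therefore cannot decide whether deeper sequencing of replicate 2 was the cause. Over the 280 and 1430 shared sites in the blocks, median log2 shifts were 0.0185 and 0.0295. Their upper bounds of 0.09 and 0.06, against 0.58 for 1 extra copy, argue against extra DNA copies as the general cause in blocks with shared sites. Blocks without a shared site were not tested, and a median over all sites cannot exclude extra copies in some blocks. Bases in the blocks were listed in the other library at 0.125 and 0.178 of the level in the library with the block, but as the longer list and the listing of bases stop at the same false discovery rate, the threshold of the calls stays open as a possible explanation, as do the local background used by the caller and stray DNA, and no biological explanation was tested.

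Chromosome Y regions in libraries given as female may come from sequence shared with other chromosomes. In replicate 1 34.0% and in replicate 2 29.0% of their stretches of 32 bp had an exact copy on another chromosome, between the 50% and the 10% that were set to decide, so shared sequence cannot be told apart from other sources. Cells of a male animal as the main source are argued against by the absence of a region at any of the 8 Y-linked promoters, Kdm5d, Uty, Ddx3y and Eif2s3y among them. A permutation test over genes, against random gene lists, gave p = 2e-04 in both libraries, the smallest that they can give. A variant of the strain against the reference was not tested.

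Promoter regions on chromosome X were weaker than those of autosomal genes of like CpG content by a log2 difference of -1.04 ± 0.04 (SD, n = 2; -1.26 before matching). Matching removed 17.5% of the difference, which argues against lower CpG content as the whole cause. The promoters of 6 genes known to be expressed from both X chromosomes (Ddx3x, Eif2s3x, Kdm5c, Kdm6a, Pbdc1 and Utp14a) had a median strength above that of other X-linked promoters by 1.73 ± 0.11 on the log2 scale, and from 6.56 ± 2.27 at Pbdc1 to 16 ± 5.25 at Kdm6a each. As values of 4 of these 6 genes had been seen when the set was chosen, and as the difference exceeds the 1 log2 unit that a silent copy allows, it cannot serve as independent evidence. A silent copy of chromosome X in female cells stays open as a possible explanation, and expression was not measured.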
